A study of Mus musculus with 11 samples.

How the data were processed

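Fragments bound by FMRP, the RNA-binding protein that is lost in Fragile X syndrome, were measured in brain tissue of mice at postnatal day 13. Per the labels' protocols, tissue was ground in liquid nitrogen and crosslinked with 3 doses of 400 mJ of ultraviolet light at 254 nm, FMRP was immunoprecipitated, the proteins were digested, and the RNA was made into libraries with a ligation kit for small RNAs. The authors deposited a table of fragment counts per gene symbol for 11 libraries. The submitters' processing notes name the build mm10, Bowtie 0.12.7 and Picard. The program that counted fragments, the gene annotation, the use of strand, the removal of duplicates and any filter on fragments are not given in the sources used here. Fragments of overlapping or antisense genes, and of near-identical copies, therefore cannot be told apart in these values.

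The deposited counts are whole numbers per row and were used as deposited. The table has 30986 rows, and 0 sample columns were left unused. Library totals ran from 11898 to 197382 counts, 712686 in all. CPM are counts divided by these totals and multiplied by 1000000. At the lowest total, 10 counts correspond to 840.5 CPM, and at the highest total to 50.7 CPM, so the shallow libraries carry wider counting error. A count of 0 allows up to 3 counts, which is 15.2 CPM in the deepest library and 252.1 CPM in the shallowest. Intervals are exact Clopper-Pearson intervals for Pde2a and Wilson intervals for shares, at the 95% level, and they cover counting error only, because fragments amplified by PCR are not independent molecules.

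Of the 11 libraries, 2 are labelled cerebellum, 3 cortex and 5 hippocampus. One further library has a title that names cortex and a tissue label that names hippocampus. It was put in no region and entered alternatives only. The labels do not say whether libraries of a region came from separate animals, so p-values measure the spread between these libraries, which may be technical. Hippocampus 1 and hippocampus 2 differed by no more than sampling noise (chi-square per degree of freedom 1.03, p = 0.191, over 1873 rows with an expected count of at least 5). The other 13 pairs of the same region had values from 1.51 to 22.1. The counts of hippocampus 1 and 2 were therefore summed and counted as 1 sample, named hippocampus 1+2, which left 9 samples: 2 cerebellum, 3 cortex and 4 hippocampus. The design fixed before the data were examined had 10 separate libraries. Summing departs from it and was decided after the fit over 10 libraries had been run and seen; that fit is kept as an alternative.

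The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM factors, the filterByExpr function by region and Benjamini-Hochberg adjusted p under 0.05. The numeric code in each sample title was a block, and all 9 samples were in one fit with 4 residual degrees of freedom. The labels do not say what the title codes stand for. Deviations from the region means correlated between samples of the same code with a median r of 0.13 over 8 pairs (from -0.067 to 0.48). Over 18 pairs of different codes the median was -0.05. These correlations are across genes, which are not independent replicates. The 2 cerebellum samples deviate from their mean by exact opposites. The r of 0.149 for cerebellum 1 with cortex 1, of the same code, thus forces -0.149 for cerebellum 2 with cortex 1. Part of the difference between the medians is therefore fixed in advance. After the filter, 1720 rows were tested. The SE given with edgeR values is the absolute log2 fold change divided by the square root of the F statistic. The test gives no standard error of its own, so this SE is approximate. The first contrast set cerebellum against the mean of cortex and hippocampus, called forebrain below, and the second set cortex against hippocampus. No input library and no library without FMRP was analysed here, so a difference in fragments can come from the amount of an RNA or from its binding.

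Before the data were examined, 31 gene lists were fixed: cell type markers, regional markers, synaptic and signalling gene groups and known FMRP-bound mRNAs. The 21 lists with at least 3 tested members were tested with camera of limma 3.58.1, with a preset inter-gene correlation of 0.01, two-sided, adjusted over 42 tests (21 lists, both comparisons), and again with an estimated correlation and with fry. For lists with fewer tested members, and for all 30 lists with rows in the table as an alternative added after seeing the data, summed CPM were compared by two-sided exact permutation over 36 splits (cerebellum) or 35 splits (cortex against hippocampus), so that p could not go below 0.0278 and 0.0286. The level of known FMRP-bound mRNAs was described by the percentile of the list's median CPM among 10000 random lists of the same size drawn from the tested rows.

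Genes are named by a rule fixed before the data were examined. It takes Pde2a, the 8 genes with the largest change per direction among those past the threshold, with at least 20 CPM in the higher region and the same sign within each title code that holds both sides, passing over predicted names. It adds the 3 members with the smallest p of a list whose camera call passes and at most 1 of any other list, the 10 rows with the highest mean CPM per region, and phosphodiesterases of at least 5 CPM. A count of 5 or fewer genes is given with the names, which were then chosen after their values were seen. Coordinates and transcript lengths come from the GENCODE annotation of GRCm38, the assembly that mm10 denotes: 23558 symbols matched directly, 435 through an older symbol, and 6992 had no gene model.

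The fit was tested on simulated counts with 200 changed genes. For the cerebellum comparison, 9.26% of genes changed by a factor of 2, 63.2% of those changed by 4 and 91.1% of those changed by 8 passed the threshold, among 54, 57 and 56 such genes that were tested. For cortex against hippocampus the shares were 11.3%, 55.2% and 92.6% of 53, 58 and 54 genes. Of the calls in these simulations, 1.08% and 3.3% were unchanged genes. All simulated genes had the common dispersion of 0.096, and samples differed only in total and in the set changes, with no title code effect. These shares are therefore not error rates of the real calls. Settings fixed beforehand for comparison were DESeq2 size factors, library totals only, no filter on low counts, a filter of at least 10 counts in every sample of at least 1 region, DESeq2 1.42.0, no block, a block on the letter before the title code, the library of conflicting labels under either label, ribosomal RNA rows left out, only libraries with s titles, only title code 150909, cortex or hippocampus alone as the reference, and each sample left out in turn. Alternatives chosen after seeing the data were the 10 libraries as separate samples, thinning to 30000 counts, leaving out the 3 samples with the lowest share of known FMRP-bound mRNAs, and the library of conflicting labels with the block on the letter.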

Results

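Brain tissue of mice at postnatal day 13 was used to recover the RNA fragments that are bound by FMRP in cerebellum, cortex and hippocampus. The series title names PDE2A, a phosphodiesterase that degrades cAMP and cGMP, in connection with Fragile X syndrome. Total counts were 95454 and 197382 in cerebellum, 30721, 55784 and 11898 in cortex, and 130306 (hippocampus 1+2), 117322, 21944 and 21531 in hippocampus. Hippocampus 1 and 2 differed by no more than sampling noise and were counted as 1 sample, a choice made after the fit over 10 separate libraries had been seen. Whether the libraries of a region come from separate animals is not given by the labels, and the intervals and floors below cover counting error only. CPM are counts per 1000000 counts of the library. A further library of 30344 counts, with conflicting labels for its region, stands outside the comparisons.

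In cortex the rows with the highest mean were Apc, a regulator of Wnt signalling and microtubules, at 7485 ± 4213 CPM (SD, n = 3), and Map1b, a microtubule-associated protein, at 5901 ± 3438 CPM. The same genes led in hippocampus, at 6291 ± 4307 and 4547 ± 3556 CPM (SD, n = 4). In cerebellum Adcy1, a calcium-stimulated adenylyl cyclase, led with 6439 ± 1784 CPM (SD, n = 2), followed by Fat2, an atypical cadherin of granule cells, with 3436 ± 919 CPM. The motor protein gene Kif1a and the ankyrin gene Ank2 were, like Apc and Map1b, among the 10 highest rows of all 3 regions, with Kif1a at 2530 ± 66.9, 4002 ± 1681 and 3197 ± 2504 CPM in cerebellum, cortex and hippocampus. Huwe1, a ubiquitin ligase, Map1a and Kif1b stood among the 10 highest in cortex and hippocampus, and Cacna1e, Itpr1 and Igsf9b among those of cerebellum.

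Messenger RNAs known from earlier work as FMRP targets stood far above other genes. The median of 58 tested members was 712.3 CPM in cerebellum, 859.1 in cortex and 669.8 in hippocampus, each at percentile 100 of 10000 random lists of the same size, whose medians centred on 187, 200.4 and 170.6 CPM. Random lists matched on transcript length, centred on 254.6, 244.1 and 217.9 CPM, left the percentile at 100 in each region. It was 100 in each single sample as well. The lists were not matched on the amount of RNA and no input library was analysed here, so this high level is no measure of binding. Of all counts, known targets took 5.33 ± 0.141% in cerebellum (SD, n = 2), 7.1 ± 3.21% in cortex (n = 3) and 5.47 ± 2.86% in hippocampus (n = 4). Within regions the samples stood apart: hippocampus 3 had 2.66% (95% Wilson interval 2.57 to 2.75%), hippocampus 4 had 3.56% (3.32 to 3.81%) and cortex 3 had 3.44% (3.13 to 3.78%), against 6.85 to 9.39% in the other 4 forebrain samples. Those 3 samples also had the largest shares of counts on predicted gene names, 18.9, 17.8 and 18.4%.

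**Figure D1:**
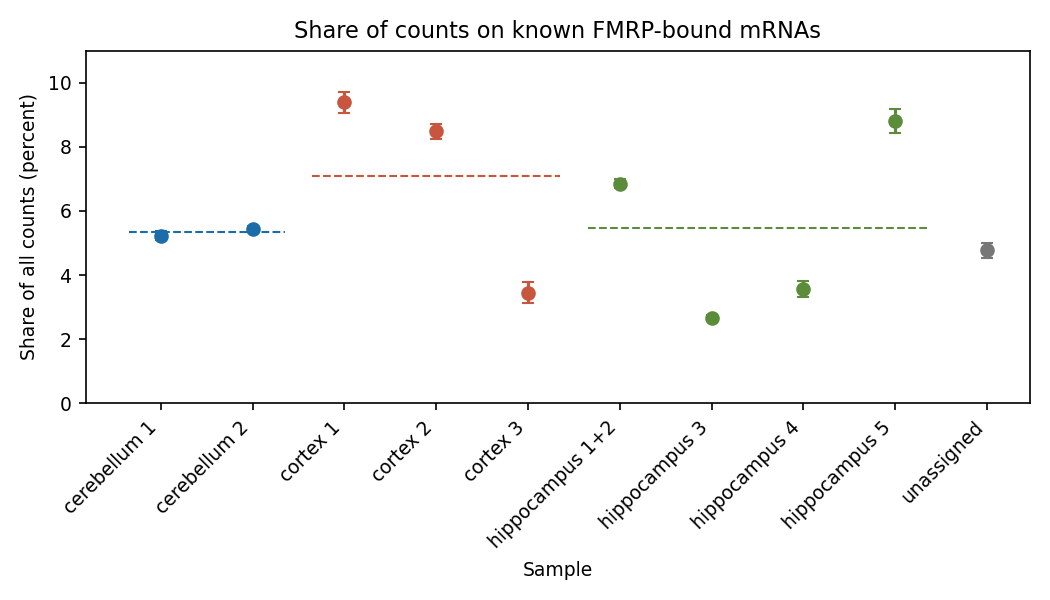
Share of all counts that fell on known FMRP-bound mRNAs, in percent, for each sample; points are samples, bars are 95% Wilson intervals, dashed lines are region means and the grey point is the library of conflicting labels. Hippocampus 3, hippocampus 4 and cortex 3 lie between 2.66 and 3.56%.

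Pde2a, at chromosome 7 from 101421691 to 101512827 on the plus strand of GRCm38, was compared between the regions because the series is named for it. Its level was 87.5 ± 5.22 CPM in cerebellum (SD, n = 2), 1143 ± 222 CPM in cortex (n = 3) and 500.2 ± 411 CPM in hippocampus (n = 4; mean 314 CPM without hippocampus 1+2). Among all rows Pde2a ranked 57, 79 and 22 in the cortex samples, and 2237 and 2074 in the cerebellum samples. Cerebellum was lower than forebrain by a log2 fold change of -2.39 (SE 0.61, adjusted p = 0.00317, edgeR). It was lower than cortex alone by -2.79 (SE 0.68, adjusted p = 0.00387, edgeR) and lower than hippocampus alone by -1.99 (SE 0.59, adjusted p = 0.0171, edgeR). The hippocampus samples were uneven, with 1059 CPM (95% interval 889.8 to 1251), 68.2 CPM (29.4 to 134.4), 455.7 CPM (218.5 to 837.9) and 418 CPM (191.2 to 793.3) in hippocampus 1+2, 3, 4 and 5. Hippocampus 3 thus stood at the level of cerebellum. Among the samples that share the title code of cerebellum 1, the log2 fold change was -3.31, and among those that share the code of cerebellum 2, where hippocampus 3 is the only forebrain sample, it was -0.15. The Pde2a call was lost without cerebellum 1 (log2 fold change -0.33, adjusted p = 0.983, with 1 cerebellum sample left and the spread taken from the other regions), without cortex 1 (-2.45, adjusted p = 0.228) and without hippocampus 5 (-2.27, adjusted p = 0.0764) in edgeR. It was also lost with library totals alone (adjusted p = 0.218), without the filter on low counts (adjusted p = 1) and with only the libraries of s titles (adjusted p = 0.229), and the value was -3.67 without hippocampus 3 (adjusted p = 1.27e-07) and -3.65 without cerebellum 2 (adjusted p = 0.019). Under the block both of these rest on cerebellum 1 alone, since either omission leaves a single sample in the title code of cerebellum 2. Without cerebellum 1, the value of -0.33 links cerebellum to forebrain only through hippocampus 3, the only forebrain sample in the title code of cerebellum 2.

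**Figure D2:**
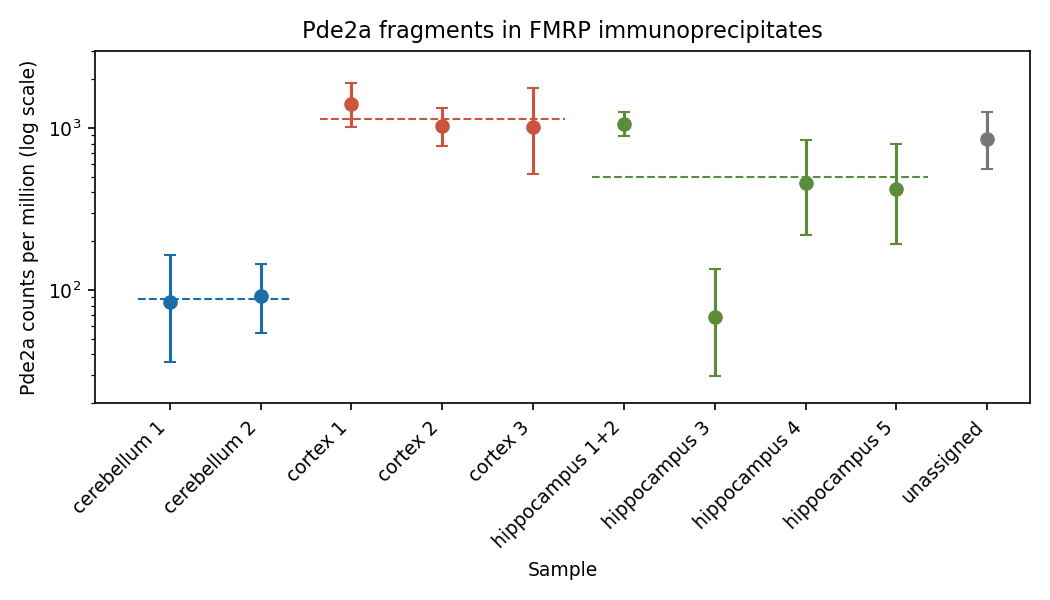
Pde2a CPM on a log scale for each sample; bars are exact 95% intervals of the count, dashed lines are region means and the grey point is the library of conflicting labels. The cortex samples lie between 1009 and 1400 CPM, the cerebellum samples at 83.8 and 91.2 CPM, and hippocampus 3 at 68.2 CPM.

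Of the 22 members of the phosphodiesterase list, only 6 passed the filter on low counts and could be called. Besides Pde2a, the other tested phosphodiesterases showed no call between cerebellum and forebrain. The nearest was Pde3a, which degrades cAMP, with 284 ± 57.7 CPM in cerebellum, 73.6 ± 9.62 CPM in cortex and 87 ± 60.9 CPM in hippocampus (log2 fold change 1.51, SE 0.61, adjusted p = 0.124, edgeR). Pde4d and Pde10a had log2 fold changes of -0.53 and 0.07, and Pde1a 0.46 with an SE of 1.18. Pde4dip, a scaffold protein gene that the list holds although it encodes no phosphodiesterase, had 0.15. Over the 6 tested members of the list, Pde4dip included, 1 was lower over all genes, and adjusted over the list alone 1 was lower and 1 higher; the list as a whole had adjusted p = 0.816 (camera). Among genes of cAMP and cGMP signalling, 1 of 16 was higher and 1 lower (the same counts adjusted over the list alone; camera adjusted p = 0.853), with Nos1, the neuronal nitric oxide synthase, higher in cerebellum by 1.89 (SE 0.57, adjusted p = 0.0158, edgeR).

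Cerebellum differed from forebrain in 132 of 1720 genes, 67 higher and 65 lower (edgeR, 310 genes at an unadjusted p under 0.05). Fat2 was higher by a log2 fold change of 5.42 (SE 0.62), with 3436 ± 919 CPM in cerebellum (SD, n = 2) against 113 ± 147 CPM in forebrain (n = 7). Grm4, the metabotropic glutamate receptor of parallel fibre terminals, was higher by 4.04 (SE 0.54), and Chd7, a chromatin remodeller, by 3.67 (SE 0.63). Il16, an interleukin precursor with a neuronal form, was higher by 4.7 (SE 0.9), and Draxin, a secreted axon guidance protein, by 4.86 (SE 1.02). Draxin had 0 counts in all cortex samples, where the floor of 3 counts over the group is 30.5 CPM, so cerebellum was at least 9.52-fold higher than cortex. Galnt15, a glycosyltransferase, Xkr7 and Chn2, a Rac GTPase-activating protein, were higher by 3.46, 3.42 and 3.25. In the other direction Bcl11b, a transcription factor of subcortical projection neurons, was lower by -4.98 (SE 0.97) and Nrgn, a calmodulin-binding postsynaptic protein, by -4.95 (SE 0.89). Camk2a, the synaptic kinase subunit, had 46.3 ± 6.19 CPM in cerebellum against 1162 ± 760 CPM in forebrain (log2 fold change -3.78, SE 0.65). The potassium channel gene Kcnh3 (-4.4), the sulfotransferase gene Chst1 (-4.21), the kinase gene Pak6 (-3.91), Stum (-3.85) and the muscarinic receptor gene Chrm1 (-3.61) were lower as well. With 10 separate libraries as first designed, 185 genes passed, 94 higher and 91 lower.

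**Figure D3:**
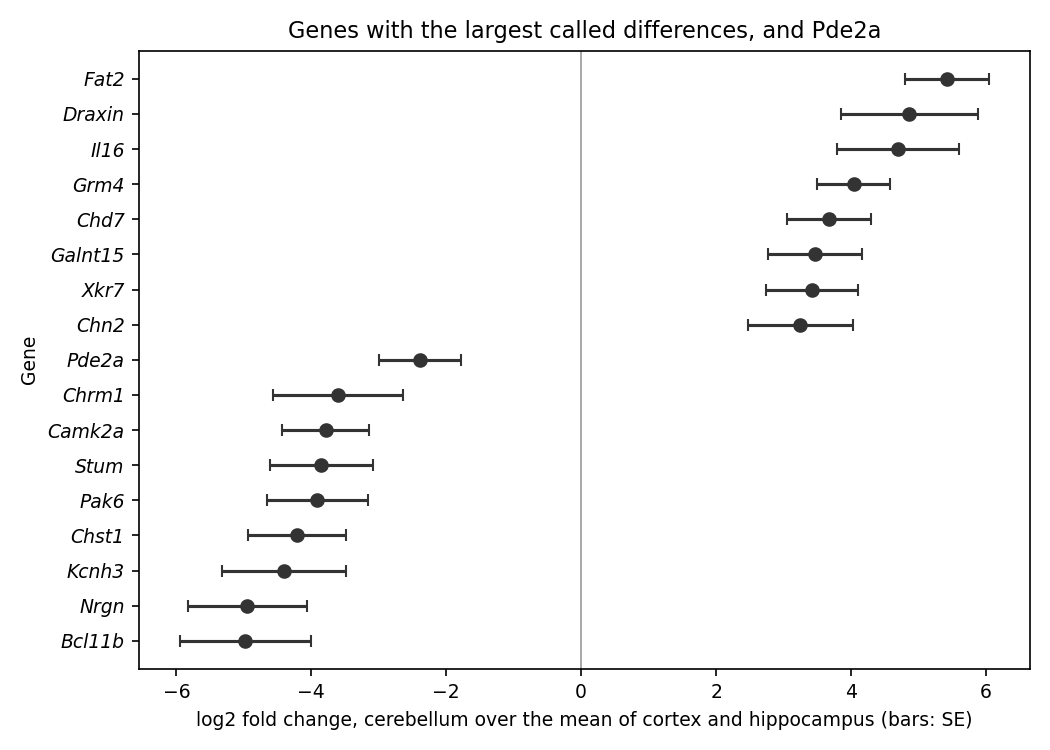
Log2 fold change of cerebellum over the mean of cortex and hippocampus for the 16 genes with the largest called differences and for Pde2a. Points are edgeR estimates and bars are the SE derived from the F statistic. Fat2 is highest at 5.42 and Bcl11b lowest at -4.98, and the estimate for Draxin depends on the prior count because cortex had 0 counts.

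Genes of cerebellar granule cells rose together in cerebellum: 6 of 7 tested members passed the threshold, all higher, and the same number adjusted over the list alone (median log2 fold change 2.5, camera adjusted p = 1.43e-07, adjusted p = 0.152 with an estimated correlation). Cadps2, a secretion factor of granule cells, was higher by 2.5 (SE 0.56, adjusted p = 0.000479, edgeR). Telencephalic excitatory neuron markers passed as a list, lower in cerebellum, with the preset correlation (camera adjusted p = 8.84e-06). They did not with an estimated correlation (camera adjusted p = 0.443). Their median was -1.63, with 4 of 16 lower over all genes and 10 adjusted over the list alone. Their leading members were Camk2a, Nrgn and Kcnh3. Cortical projection neuron markers also passed as a list, lower in cerebellum, with the preset correlation (camera adjusted p = 0.00559). They did not with an estimated correlation (camera adjusted p = 0.483). Their median was -1.3, and 1 of 8 was lower, 2 adjusted over the list alone. Bcl11b passed, and Foxp1 (-1.78, adjusted p = 0.0892) and Slc17a7 (-1.1, adjusted p = 0.173) did not in edgeR. Postsynaptic scaffold genes fell as a list, with 6 of 32 lower and 2 higher, and 9 and 2 adjusted over the list alone (median -0.49, camera adjusted p = 0.00294, adjusted p = 0.525 with an estimated correlation). Lrrc7, a densin that binds the kinase of Camk2a, was lower by -1.94 (SE 0.52) and Sipa1l1, a spine GTPase-activating protein, by -2.14 (SE 0.57). Without cerebellum 1, which leaves 1 cerebellum sample, the call was lost for the scaffold list (camera adjusted p = 0.157) and for the cortical list (0.0998). Within the title codes of cerebellum 1 and cerebellum 2, the log2 ratios of summed CPM were 2.72 and 2.69 for granule cell markers, -1.15 and -0.38 for telencephalic excitatory markers and -0.96 and -0.24 for cortical projection markers. For scaffold genes they were -0.95 and 0.25. These sums use library totals without TMM factors, unlike the list test. The factors were 0.9825 in cerebellum 2 and 0.6442 in hippocampus 3, the only forebrain sample of its code. Applying them would raise hippocampus 3 against cerebellum 2, so the change of sign may come from the scale.

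Summed over all members, granule cell markers took 9222 ± 1255 CPM in cerebellum (SD, n = 2) against 1480 ± 140 CPM in forebrain (n = 7), and Purkinje cell markers 4392 ± 537 against 1597 ± 277 CPM. GABAergic interneuron markers took 3320 ± 446 against 1820 ± 322 CPM. For each of these the exact permutation p was 0.0278, the smallest that 36 splits allow, and 0.286 adjusted over 60 tests. Purkinje cell markers had 2 higher and 1 lower of 5 tested members, and 3 and 1 adjusted over the list alone (camera adjusted p = 0.105; 0.0439 without cerebellum 2 or without hippocampus 3, where cerebellum 1 alone informs the contrast, 0.0484 without hippocampus 5), with Itpr1, the inositol trisphosphate receptor, higher by 2.33 (SE 0.52, adjusted p = 0.000479, edgeR). Interneuron markers had 1 higher, the secreted glycoprotein gene Reln (1.93, SE 0.5, adjusted p = 0.0037, edgeR), and 1 lower of 6, and 4 and 2 adjusted over the list alone (camera adjusted p = 0.509). Astrocyte markers had 2 of 12 lower, also adjusted over the list alone (camera adjusted p = 0.239); among them the glutamate transporter gene Slc1a2 was lower by -2.41 (SE 0.64, adjusted p = 0.00511, edgeR). Of 3 tested oligodendrocyte markers 0 passed, also adjusted over the list alone (camera adjusted p = 0.707).

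Known FMRP-bound mRNAs did not pass as a list between cerebellum and forebrain: 1 of 58 was higher and 5 lower, and 1 and 6 adjusted over the list alone (median -0.04, camera adjusted p = 0.239, adjusted p = 0.931 with an estimated correlation). The list passed, lower in cerebellum, without cerebellum 2 or without hippocampus 3 (camera adjusted p = 0.000763) and without the 3 samples of lowest known share (0.00158, chosen after seeing the data). These are not separate results: under the block each rests on cerebellum 1 as the only cerebellum sample that informs the contrast. The title codes differed in direction on library totals, without TMM factors. The log2 ratio of summed CPM was -0.62 in the code of cerebellum 1 and 1.03 in that of cerebellum 2. The lower TMM factor of hippocampus 3, 0.6442 against 0.9825 in cerebellum 2, would make the second ratio smaller. Voltage-gated calcium and sodium channel genes had 2 of 12 higher, and 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.136; 0.0317 without the block), with Cacna1g, a T-type calcium channel gene, at 1.8 (SE 0.49, adjusted p = 0.00569, edgeR). Among potassium channel genes 1 of 17 was higher and 3 lower, and 2 and 4 adjusted over the list alone (camera adjusted p = 0.239; 0.0345 without cerebellum 1). Glutamate receptor genes had 3 of 17 higher and 1 lower, and 4 and 1 adjusted over the list alone (camera adjusted p = 0.853); their median was -0.68 and their mean 0.06.

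The count for cerebellum moved with the samples: it was 2 without cerebellum 1 (Chst1 and Bcl11b, chosen after their values were seen), 17 without cerebellum 2, 15 without cortex 1 and 81 without hippocampus 1+2. With either cerebellum sample left out, cerebellum has 1 sample and the other regions supply the spread. Those counts may therefore also reflect the smaller design, which was not tested. Under the block, leaving out hippocampus 3 keeps the same samples that inform the contrast as leaving out cerebellum 2. Its count was nevertheless 97, of 1148 tested genes, against 1994 genes tested without cerebellum 2. The low count without cerebellum 2 thus cannot be put down to the loss of that sample alone. The count for cerebellum was 1 without the filter on low counts. With library totals alone it was 54, 37 higher and 17 lower, and the median of all genes moved to 0.12.

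Between cortex and hippocampus, 0 of 1720 genes passed the threshold in edgeR, against 68 at an unadjusted p under 0.05, and DESeq2 called 1 gene, Zbtb20. Zbtb20, a transcription factor of hippocampal neurons, had 278.1 ± 95.5 CPM in cortex (SD, n = 3) and 984 ± 659 CPM in hippocampus (n = 4), a log2 fold change of -2.03 (SE 0.51, adjusted p = 0.0791, edgeR). Its value was -2 within the title code of cortex 1 and -1.94 within that of cortex 2 and 3. Prox1, a factor of dentate granule cells, stood at 17.9 ± 31.1 against 195.6 ± 57.8 CPM (-3.17, SE 0.97, adjusted p = 0.41, edgeR). Pde2a was 0.8 higher in cortex (SE 0.43, adjusted p = 0.999, edgeR), 0.09 within the title code of cortex 1 and 1.04 within that of cortex 2 and 3.

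Hippocampal neuron markers were lower in cortex as a list of 10 (median -1.21, camera adjusted p = 0.00294, adjusted p = 0.443 with an estimated correlation), with 0 members past the threshold over all genes and 2 lower adjusted over the list alone. Besides Zbtb20 and Prox1, the mineralocorticoid receptor gene Nr3c2 had -1.77 (SE 0.9, adjusted p = 0.999, edgeR). Between cerebellum and forebrain the same list did not pass (median 0.295, camera adjusted p = 0.707). Of its 10 members 1 was higher in cerebellum, Il16, and 1 lower, also adjusted over the list alone. Zbtb20 had 925.4 ± 69.2 CPM in cerebellum (SD, n = 2), a log2 fold change of 0.006 over hippocampus (SE 0.48, edgeR). Cortical projection neuron markers were higher in cortex as a list of 8 (median 0.77, camera adjusted p = 0.00595, adjusted p = 0.483 with an estimated correlation), with 0 past the threshold over all genes and 2 higher adjusted over the list alone. Plxnd1, a semaphorin receptor gene, had 1.66 (SE 0.58, adjusted p = 0.694, edgeR), the transcription factor genes Mef2c 1.47 (SE 0.54, adjusted p = 0.845, edgeR) and Foxp1 0.97 (SE 0.62, adjusted p = 0.999, edgeR). The call of the cortical list was lost without cortex 2 (camera adjusted p = 0.142) and without hippocampus 5 (0.139). Zbtb20 passed without hippocampus 3 (-2.1, adjusted p = 0.000157, edgeR) and with hippocampus 1 and 2 as separate samples (-2.09, adjusted p = 0.00505, edgeR). Known FMRP-bound mRNAs had 0 of 58 past the threshold, also adjusted over the list alone (median 0.09, camera adjusted p = 0.286; 0.0236 without cortex 3). Potassium channel genes had 0 of 17, also adjusted over the list alone (median 0.26, camera adjusted p = 0.0966; 0.0355 without cerebellum 1, 0.0399 without cerebellum 2 or without hippocampus 3), with Kcnh1 at 1.75 (SE 0.67, adjusted p = 0.89, edgeR).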

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

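The test of cerebellar markers, the tests of depth and the test of ribosomal protein genes in this part were chosen after the results were seen; the tests of length with GC content and of the share as a covariate were written before theirs.

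Over the 99 quantities checked for a hippocampus sample far from the other 3, chance alone flags about 1 in 20, and 1 was found. Ank1, an ankyrin gene that was higher in cerebellum than in forebrain by 2.38 (SE 0.55, adjusted p = 0.000863, edgeR), had 273.4 CPM in hippocampus 4 against 92.9 to 115.1 CPM in the other hippocampus samples. The library of conflicting labels, which enters no comparison, had 856.8 CPM of Pde2a (exact 95% interval 559.8 to 1255), above the 98.9 CPM that a count of 0 allows.

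The differences of the 132 genes between cerebellum and forebrain could come from technical causes, since depth differed between samples and cerebellum 2 was the deepest. Libraries were thinned to at most 30000 counts, and 77 of these genes were still tested. Their median ratio of thinned to full log2 fold change was 1.04 (quartiles 0.891 and 1.17), and 49 still passed. Random thinning leaves the expected share of each row unchanged, so a ratio near 1 was likely with or without a depth effect. The ratio therefore decides nothing, and depth stays open. Removing the trend on transcript length and GC content, which accounted for 3.6% of the variance, moved the tested genes by a median of 0.12 and left a median ratio of 0.977 over 131 genes, which argues against that trend as the source. With the share of known FMRP-bound mRNAs as a covariate, the median ratio was 1.0 over 132 genes, but the covariate moved the tested genes by a median of only 0.018 and so decides nothing, and an uneven share of known FMRP-bound mRNAs stays open. It also stays open whether the regions differ in the amount of these RNAs or in their binding, since no input library was analysed here.

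Hippocampus 3 had a low level of Pde2a and a low share of known FMRP-bound mRNAs, 2.66%. These did not go together elsewhere: hippocampus 4, with a share of 3.56%, had 455.7 CPM of Pde2a, and cortex 3, with 3.44%, had 1009 CPM. A low share thus need not come with low Pde2a. Depth alone is argued against by hippocampus samples of near depth with unlike shares. Hippocampus 1+2 had 130306 counts and a share of 6.85%, against 117322 counts in hippocampus 3. Hippocampus 4 and 5 had 21944 and 21531 counts and shares of 3.56 and 8.8%. Hippocampus 1+2 is the only other deep hippocampus sample, so this rests on few samples. Cerebellar tissue under a hippocampus label is argued against by the granule cell markers, which summed to 1296 CPM in hippocampus 3, against 8334 and 10110 CPM in cerebellum and 1345 to 1641 CPM in the other forebrain samples. A larger part of unbound cellular RNA may contribute but was not decided: ribosomal protein genes differed by a log2 ratio of 0.11 from the mean of the other hippocampus samples, and without an input library no bound can be set. No biological explanation was tested, because the labels name no biological difference between the hippocampus samples; hippocampus 3 is the only one of its title code, whose meaning is not given.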

How the results depend on the processing

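Alternatives chosen after seeing the data were separate samples for hippocampus 1 and 2, thinning, leaving out the 3 samples with the lowest known FMRP share, and the conflicting library with the block on the letter. For cerebellum against forebrain, 132 genes became 54 with library totals only, 1 (Gabra6) without the filter, 76 with a filter of at least 10 counts in every sample of any region, which tested 1931 genes, 87 with DESeq2, 85 with s titles only and 79 against cortex alone. They became 56 with thinned libraries, 215 without the 3 samples of low share, where under the block cerebellum 1 alone informs the contrast, and 81 without hippocampus 1+2. Summing hippocampus 1 and 2 was decided after seeing the fit over the 10 libraries as designed, which gave 185 genes, 94 higher and 91 lower, of which 131 were among the 132. With no replicate block the count was 156, of which 106 were shared. Leaving out each sample gave 2 to 176.

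For cortex against hippocampus, 0 genes became 1, Zbtb20, with DESeq2 size factors, with DESeq2, with thinned libraries, with hippocampus 1 and 2 as separate samples, without hippocampus 3, with the conflicting library under either label, and with it as cortex under the block on the letter. Without the 3 samples of low share 3 passed (Zbtb20, Epha6 and Kcnh1), and leaving out each sample gave 0 to 1. Under the title code block the conflicting library is the only one of its code, so either label gave equal values. The fit of the title code of cortex 2 and 3 alone holds no cerebellum and could run only here, with 0 genes. Library totals moved the median of all genes from -0.04 to 0.24.

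Pde2a in cerebellum kept its sign in all alternatives run and lost its call with library totals (-2.24), without the filter (-1.97) and with s titles only (-2.14). Leaving out each sample gave -3.67 to -0.33. Between cortex and hippocampus it passed in no alternative, from 0.52 to 1.48 when each sample was left out. With no replicate block the Pde2a values were -2.99 and 0.89, with no change of either call. Mean Pde2a CPM ran from 83.8 to 91.2 in cerebellum, 1015 to 1211 in cortex and 314 (without hippocampus 1+2) to 644.3 in hippocampus when each sample was left out. Percentiles of known targets stood at their ceiling of 100 and could show no change. The cause of these changes was not tested.

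Of 2052 values under alternatives, 1813 were unchanged in their call, 188 weaker, 30 stronger, 21 counts moved by more than 1.5 times or away from 0, and 0 changed sign while past the threshold. The unchanged values include results that did not pass in the main fit and again did not pass, and percentiles at their ceiling. Their number is therefore no measure of how stable the called results are. Of 31 named genes called in cerebellum, 2 still passed without cerebellum 1, 8 without cerebellum 2, 11 without cortex 1, 25 of the 28 still tested without hippocampus 1+2, 23 of the 27 still tested without hippocampus 3, and 23 to 31 without any other sample. All list calls were lost with an estimated correlation and with fry (granule cell markers adjusted p = 0.0527). Summed counts had little room to pass, since their smallest p is 0.0278, or 0.286 adjusted for the lists that reached it, granule cell markers among them. Of 630 list values, 22 were weaker and 17 stronger.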

Other observations

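The test of other splits was chosen after the results were seen; the test of choroid plexus markers other than Ttr was fixed before its result was seen. Immediate early genes, transcripts induced by neuronal activity, took 504.4 ± 31.8 CPM in cerebellum (SD, n = 2) and 830 ± 238 CPM in forebrain (n = 7; exact permutation p = 0.0556, adjusted p = 0.417). Noncoding RNAs of high abundance took 4029 ± 1416 against 5952 ± 2460 CPM (exact permutation p = 0.361, adjusted p = 0.686), with 1 of 11 tested lower, also adjusted over the list alone (camera adjusted p = 0.146; 0.0317 without the block, 0.0336 without cerebellum 1). Among them Meg3, an imprinted RNA, was lower in cerebellum by -2.15 (SE 0.57, adjusted p = 0.00511, edgeR). Ribosomal protein genes, which are short and abundant in all cells, took 1043 ± 201 against 1012 ± 202 CPM (exact permutation p = 0.833).

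Among 28 chromatin and transcription regulators known as FMRP targets, 26 were tested. As a list they pointed higher in cerebellum without passing (median 0.5, camera adjusted p = 0.0966, and 0.0474 without cortex 1). The list also passed without cerebellum 1, which leaves 1 cerebellum sample. Under the block hippocampus 3 is then the only forebrain sample that shares a title code with cerebellum. On library totals the log2 ratio of summed CPM was -0.09 in the code of cerebellum 1. It was 1.51 in the code of cerebellum 2, where hippocampus 3 is the only forebrain sample. Of single members 1 was lower in cerebellum, also adjusted over the list alone. It was Chd5, a chromatin remodeller of neurons, at -1.76 (SE 0.54, adjusted p = 0.0172, edgeR). Presynaptic release genes had 1 of 29 higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.424), with Unc13c, a priming factor of cerebellar granule cells, higher by 1.72 (SE 0.51, adjusted p = 0.014, edgeR). Genes of autophagy, mTOR and translation control had 0 of 19 past the threshold (camera adjusted p = 0.796), with Ago1 at 0.94 (SE 0.62, adjusted p = 0.484, edgeR). Microtubule motor and cytoskeleton genes had 2 of 31 higher, also adjusted over the list alone (camera adjusted p = 0.734; 0.0345 without cerebellum 1). GABA receptor subunit genes had 1 of 6 lower, Gabra5, at -3.3 (SE 0.92, adjusted p = 0.00762, edgeR).

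Markers of the choroid plexus, the epithelium of the ventricles, took 179 ± 127 CPM in cortex (SD, n = 3) and 547.7 ± 208 CPM in hippocampus (SD, n = 4; two-sided exact permutation p = 0.0286, the smallest that 35 splits allow, adjusted p = 0.286). A candidate explanation is choroid plexus tissue carried along with hippocampus. Its most abundant transcript, Ttr, had 16.8 ± 16.3 against 269.3 ± 207 CPM and a log2 fold change of -3.88 (SE 0.99, adjusted p = 0.0791, edgeR). The 12 other members, summed, had 162.1 ± 124 against 278.4 ± 184 CPM, a log2 ratio of -0.78 (exact permutation p = 0.457), with -1.33 within the title code of cortex 1 and 0.27 within that of cortex 2 and 3. The explanation thus stays open, and the counts behind it are few, from 1 to 64 per sample for these 12 genes.

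Of the 35 splits of the 7 cortex and hippocampus samples into 3 and 4, 34 could be fitted with the title code block. The real split called 0 genes, so all 34 splits reach it by necessity and the count of calls says nothing about chance; the highest other split called 23 genes. At an unadjusted p under 0.05 the real split had 68 genes, 12 of the 34 splits, the real one included, had at least as many, and the highest other had 247. Chance cannot be excluded for those 68 genes. The split with 23 calls set hippocampus 3, hippocampus 4 and cortex 3 against the rest, the samples with the lowest shares of known FMRP-bound mRNAs, which points to a structure of the samples other than region.

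In the library of conflicting labels, known FMRP-bound mRNAs took 4.77% of counts (95% Wilson interval 4.54 to 5.01%). Cortical projection neuron markers summed to 3296 CPM there, and hippocampal neuron markers to 2340 CPM. In cortex these lists took 3288 to 4284 and 1429 to 2868 CPM, and in hippocampus 1672 to 2594 and 2917 to 5202 CPM.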
